A study of Homo sapiens with 8 samples.

How the data were processed

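RNA sequencing was done on 8 libraries of mesenchymal stromal cells derived from H9, an established human embryonic stem cell line. Total RNA was isolated with a miRNeasy kit and libraries were made with standard Illumina protocols, per the labels' protocols. The submitters' processing notes name CASAVA 1.9, TopHat with its version given as 12.0.6, HTSeq and the human genome build hg19. The annotation release, the strand setting and the counting of read mates are not given in the sources used here.

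The deposited table gives 1 count and 1 RPKM value for each gene and library, per the file headers. The counts were taken as the authors deposited them, as whole numbers with no normalisation. Every one of them is even, with 0 odd values. No source says why. Intervals on single libraries assume that each counted unit, such as a read pair, was entered as 2. The RPKM values were computed by the authors per kilobase of coding length, scaled to a library total. That total is larger than the sum of the counts, and the deposited RPKM values were used only to recover it. Positions are those of the deposited table in hg19 coordinates. The table held 23398 entries. Of 49 gene identifiers listed more than once, 41 repeated identical counts and were kept once, and 8 carried different counts and were kept as separate entries, which left 23354 genes. No entry lay on the mitochondrial chromosome, so the share of mitochondrially encoded RNA was not analysed here. No entry stood for reads without a gene.

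Groups were taken from the sample titles: 3 fresh libraries, 2 libraries frozen in DMSO and 3 libraries frozen in solutions labelled SMC, SGC and SGI. No library was left out. Pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom from 6.84 to 78.08 over genes, so none was counted as a repeat of another. The sum of counts ranged from 41198716 to 51166666 per library. No values beyond those of the 8 libraries were used.

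Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr by state, fresh or frozen, which kept 15564 genes. Library sizes were scaled by the trimmed mean of M-values (TMM). Fits used glmQLFit with robust estimation and tests used glmQLFTest, with Benjamini-Hochberg (BH) adjustment at 0.05. Frozen and fresh libraries were compared in a fit with 2 states and 6 residual degrees of freedom. The 3 pairwise comparisons of fresh, DMSO-frozen and osmolyte-frozen libraries came from 1 fit of 3 groups with 5 residual degrees of freedom. The DMSO difference came from an additive fit of state and DMSO, and the interaction of DMSO and freezing from a fit with 4 residual degrees of freedom, to which the lone fresh library with DMSO gives no spread of its own. The biological coefficient of variation was 0.154 in the fit of 2 states, 0.0971 in that of 3 groups and 0.110 in the additive fit. A standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM, counts scaled to a common library size with the TMM factors, as mean ± SD.

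Gene lists of cell type markers, stress responses and cell programmes were fixed before the data were examined, 35 in all. They were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2, once with a preset correlation between genes of 0.01 and once with an estimated correlation, and with fry, with BH adjustment over the lists. The list tests fixed beforehand were those of frozen against fresh, osmolyte against DMSO, and DMSO against no DMSO. The list tests of the other 3 comparisons were added later, when the scripts were written. Members past the threshold were counted over all genes tested and also adjusted over the list alone. Conditions with 1 library each were compared as pairs by the log2 ratio of CPM with a prior count of 2, with no test. The prior count shrinks the folds of weakly expressed genes, so these can be smaller than the ratio of the printed levels. For these, genes at least 2-fold apart with a count of at least 50 in the higher library were counted, and a list's median was placed among the medians of 10000 random lists matched on mean expression. The random genes were drawn independently, so a list whose genes vary together can reach an extreme percentile through a small shared shift. Shares of counts per library were compared between 5 frozen and 3 fresh libraries with a two-sided exact permutation test over 56 splits. Intervals of 95% on single-library values are exact Poisson intervals. They cover counting error only, since reads without molecular identifiers are not independent molecules.

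The genes to be named followed a rule fixed before the data were examined. For each tested comparison these were, among genes past the threshold whose libraries did not overlap between the sides compared and with a mean of at least 5 CPM on the higher side, the 12 with the largest rise and the 12 with the largest fall. The rule did not ask for separate libraries in the DMSO fit, and the scripts did not ask for it in the interaction either. Some genes that the rule picks are not reported here. Up to 4 members with the smallest p were added from each list, and for each pair the 5 largest rises and falls with a count of at least 200 in the higher library. Genes that share reads with a near-identical copy are uncertain where counting could split them, which applies to ACTA2 and ACTG2, to POU5F1 with its processed copies, and to ribosomal protein genes. Because strand use is not given, reads of a gene and of an overlapping antisense gene cannot be told apart.

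The scripts were tested on simulated counts for the real genes with 200 genes changed by known factors. For genes changed 2-fold, 77.3% were recovered in the osmolyte against DMSO comparison over 15398 genes, 83.6% for frozen DMSO against fresh over 15412, 82.1% for osmolyte against fresh over 15383, 72.7% for frozen against fresh over 15405, 78.8% for DMSO against no DMSO over 15384 and 68.7% for the interaction over 15383. For the osmolyte against DMSO comparison 59.7% were recovered at 1.5-fold and 90.9% at 4-fold. The share of false calls ranged from 3.03% for frozen against fresh to 12.7% for the interaction. In a simulation of the DMSO comparison with 15564 genes, in which only the immediate early genes were lowered 2-fold, camera with the preset correlation called that list and 2 other lists, of 35 lists tested.

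Alternatives fixed before the data were examined were RLE size factors in edgeR, library totals alone, no filter, a filter of 1 CPM in 3 libraries and DESeq2 1.42.0 as the test. Also fixed then were fits without robust estimation, hold time as a covariate, other sets of libraries and an estimated correlation for lists. The last were other prior counts and count minimums for pairs, and leaving out each library in turn. Halved counts, leaving out each library for the gene lists, and the sum of counts as a share of the RPKM library total were added after seeing the data. GC content and strand came, by gene symbol, from a GENCODE annotation of another genome build, which was used for no coordinates.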

Results

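Gene expression was measured by RNA sequencing in mesenchymal stromal cells derived from H9, an established human embryonic stem cell line, before and after freezing. The series held 8 libraries, each of a different condition: 3 of fresh cells, 2 of cells frozen in DMSO and 3 of cells frozen in multicomponent osmolyte solutions. The fresh libraries were from cells at 0 h, after 1 h with DMSO and after 1 h in medium. Cells frozen in DMSO were held for 0 h or 1 h, those in the solutions labelled SGC and SGI for 1 h and those in SMC for 2 h. Counts summed to 45235900 for fresh 0 h, 43810894 for fresh 1 h DMSO and 41198716 for fresh 1 h medium. They summed to 41903498 for frozen SMC, 44359714 for frozen SGC, 43158014 for frozen SGI, 47299694 for frozen 1 h DMSO and 51166666 for frozen 0 h DMSO. As each condition had 1 library and the labels do not say whether libraries came from separate cultures, p-values here measure only the spread between libraries of differing conditions, which may be technical. Solution and cooling rate went together, since the osmolyte solutions and DMSO were cooled at different rates.

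The first principal component of log2 expression held 49.7% of the variance and set the 3 osmolyte-frozen libraries, at 36.4 to 39.9, apart from the fresh libraries, at -31.3 to -26, with the DMSO-frozen libraries at -12.8 and -15.5. The second component held 14% and was highest in fresh cells after 1 h in medium, at 32.2.

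**Figure D1:**
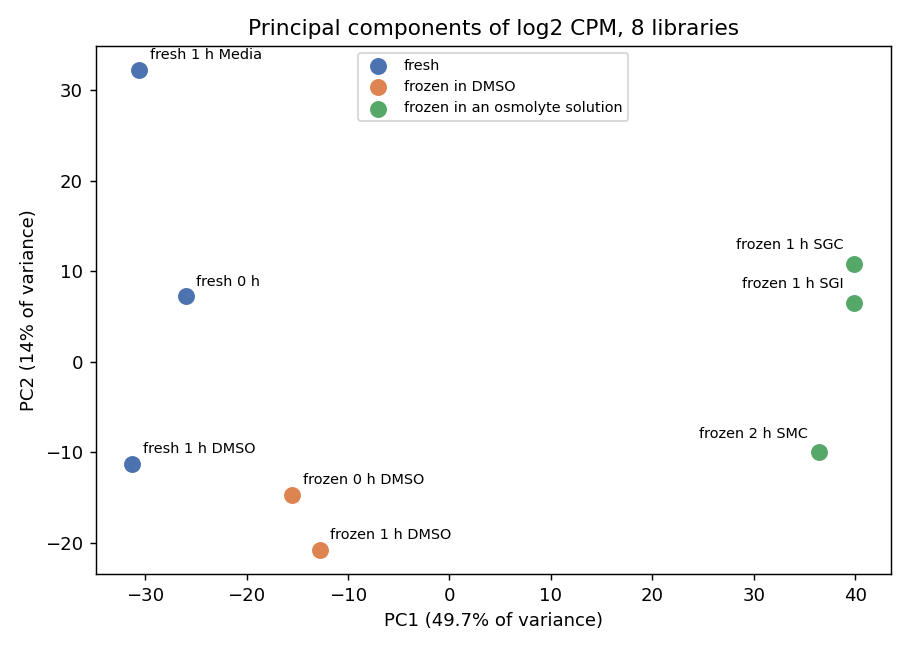
Positions of the 8 libraries on the first principal component (horizontal axis, 49.7% of the variance) and the second (vertical axis, 14%) of log2 CPM, with 1 point per library and colours for the 3 groups. The osmolyte-frozen libraries lie at 36.4 to 39.9 on the first component and the DMSO-frozen ones at -12.8 and -15.5.

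The comparison of osmolyte-frozen with DMSO-frozen cells asks how expression after freezing differs between the experimental solutions and the conventional one. ELN, which encodes elastin, the main protein of elastic fibres, was 10.96-fold higher in osmolyte-frozen cells, at 38.6 ± 6.53 CPM (SD, n = 3) against 3.52 ± 0.579 CPM (SD, n = 2). NUPR1, a stress-induced nuclear protein, was 6.09-fold higher, at 8.88 ± 0.691 CPM (SD, n = 3) against 1.46 ± 0.223 CPM (SD, n = 2). CHAC1, an enzyme that degrades glutathione, was 5.81-fold higher, at 13.4 ± 4.51 CPM (SD, n = 3) against 2.31 ± 0.256 CPM (SD, n = 2). In the other direction, ENPP2, which encodes autotaxin, the enzyme that makes lysophosphatidic acid, was 4.22-fold lower, at 2.80 ± 0.504 CPM (SD, n = 3) against 11.8 ± 0.138 CPM (SD, n = 2). HAS2, a hyaluronan synthase, was 3.23-fold lower, at 4.62 ± 1.57 CPM (SD, n = 3) against 14.998 ± 0.797 CPM (SD, n = 2). By edgeR quasi-likelihood with Benjamini-Hochberg adjustment, the log2 fold change was 3.45 (SE 0.17, adjusted p = 1.40e-09) for ELN. By the same edgeR test the adjusted p was 5.30e-08 for NUPR1, 3.12e-05 for CHAC1, 2.11e-07 for ENPP2 and 0.00167 for HAS2. In hg19, ELN lies on chromosome 7 from 73442427 to 73484236 and ENPP2 on chromosome 8 from 120569317 to 120651106. LINC00312 rose 5.90-fold, KRT17, a keratin, 5.59-fold, INHBB, the beta B subunit of inhibin and activin, 5.35-fold, ADM2, a peptide of the adrenomedullin family, 5.02-fold, and ITIH3, a hyaluronan-binding plasma protein, 4.89-fold. CCND2, a D-type cyclin, rose 4.69-fold, FLJ35282 3.95-fold, PRR15 3.86-fold and NTN1, the guidance protein netrin 1, 3.61-fold. PLEKHA6 fell 3.96-fold, TRH, the precursor of thyrotropin-releasing hormone, 3.85-fold, and SCN3A, a sodium channel subunit, 3.75-fold. ANGPT1, a ligand of the TIE2 receptor, fell 3.69-fold, CHI3L1, a secreted glycoprotein, 3.65-fold, and NMNAT2, an enzyme of NAD synthesis, 3.43-fold. LOC152742 fell 3.26-fold, MYPN 3.20-fold, THSD7A 3.16-fold and IL1R1, an interleukin 1 receptor, 3.01-fold.

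**Figure D2:**
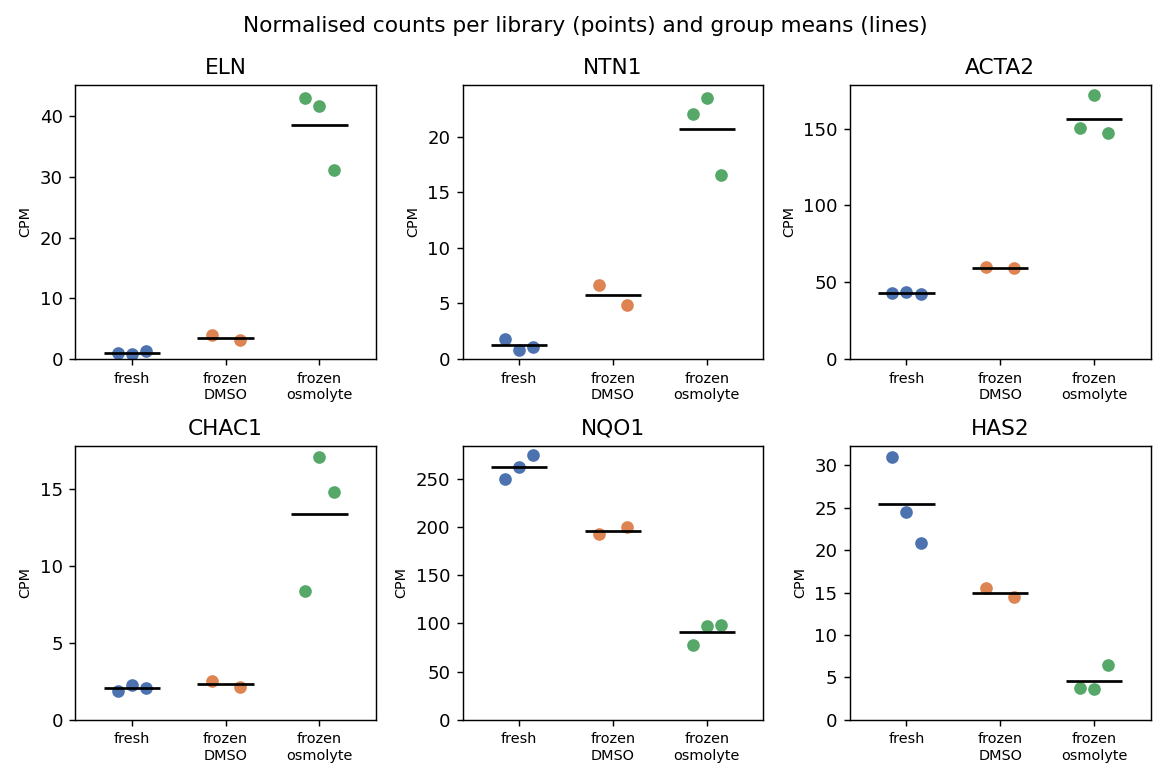
Levels of ELN, NTN1, ACTA2, CHAC1, NQO1 and HAS2 in CPM (vertical axes, linear from 0), with 1 point for each of the 8 libraries by group and lines at group means. ELN averaged 38.6 CPM in osmolyte-frozen and 3.52 CPM in DMSO-frozen libraries.

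Among muscle and contractile genes, 10 of 14 rose in osmolyte-frozen cells, and 10 rose adjusted over the list alone. ACTA2, smooth muscle actin, was 2.63-fold higher, ACTG2, a close relative whose reads may be split with it, 2.65-fold, CNN1, the actin-binding calponin 1, 2.14-fold and TAGLN, transgelin, 1.63-fold. The list was higher by limma camera with a preset correlation (adjusted p = 5.06e-07), and limma camera gave adjusted p = 0.139 with an estimated correlation. Of 24 genes of the amino acid response, which cells use when amino acids run short, 15 rose, with 16 rising adjusted over the list alone. They included CHAC1, CEBPG at 1.62-fold and SLC3A2, a subunit of amino acid transporters, at 1.64-fold. The adjusted p by limma camera was 2.49e-08, and adjusted p = 0.363 with an estimated correlation. Of 74 ribosomal protein genes, 41 rose, with 52 rising adjusted over the list alone and a median log2 change of 0.27. By limma camera the adjusted p was 3.28e-11, and adjusted p = 0.675 with an estimated correlation. Of 27 genes of the actin cytoskeleton or targets of the YAP or SRF factors, 11 rose and 4 fell, against 14 and 5 adjusted over the list alone. ANKRD1, a YAP target, rose 3.29-fold and FLNC, a filamin, fell 1.79-fold. Limma camera placed this list higher (adjusted p = 0.00454, and adjusted p = 0.662 with an estimated correlation). Of 19 TGF-beta targets, 5 rose and 1 fell, and the same numbers did so adjusted over the list alone. CDKN2B, an inhibitor of the cell cycle, rose 2.34-fold and TGFBI, a secreted adhesion protein, fell 1.96-fold. With limma camera this list had an adjusted p of 0.00338, and adjusted p = 0.662 with an estimated correlation.

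Genes of the response to oxidants driven by NRF2 were lower, with 13 of 25 falling and 2 rising, and 13 falling and 3 rising adjusted over the list alone. NQO1, a quinone reductase, fell 2.16-fold, from 197 ± 5.47 CPM (SD, n = 2) in DMSO-frozen to 91.1 ± 11.8 CPM (SD, n = 3) in osmolyte-frozen cells. SOD2, the mitochondrial superoxide dismutase, fell 1.91-fold and TXNRD1, a thioredoxin reductase, 1.61-fold. Tested by limma camera, the list had an adjusted p of 0.00170 for the list, and adjusted p = 0.267 with an estimated correlation. Among hypoxia and glycolysis genes, 11 of 28 fell and 4 rose, with 13 falling and 4 rising adjusted over the list alone. CA12, a carbonic anhydrase, fell 2.59-fold and HIF1A, the oxygen-regulated factor, 2.08-fold. The adjusted p by limma camera was 0.00199, and adjusted p = 0.267 with an estimated correlation. Of 40 genes of S phase and mitosis, 19 fell, with 21 falling adjusted over the list alone. RRM1, a subunit of ribonucleotide reductase, fell 1.58-fold, MCM6, part of the replicative helicase, 1.39-fold and TOP2A, a topoisomerase, 1.44-fold. By limma camera the adjusted p was 2.99e-06, and adjusted p = 0.662 with an estimated correlation. Of 21 genes of osmotic stress and osmolyte transport, 7 fell and 1 rose, also adjusted over the list alone. SLC6A6, the taurine transporter, fell 1.88-fold and LRRC8C, a subunit of volume-regulated anion channels, 1.96-fold. With limma camera this list had an adjusted p of 0.0413, and adjusted p = 0.662 with an estimated correlation.

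Immediate early genes, which cells switch on within minutes of a stimulus, had a median log2 change of 0.83, with 5 of 42 rising, and 3 rising adjusted over the list alone. The members past the edgeR threshold were EGR2, IER5, SRF and ZFP36L1 and, chosen after its value was seen, GADD45B. By DESeq2 12 of 42 rose, and over all 15564 genes edgeR called 2121 higher. The fit shares its spread with the fresh libraries, which differed widely in this list, so members with larger changes could fail to pass. DUSP1, an example chosen after its values were seen, did not pass. Its log2 CPM was 7.15 to 8.62 in osmolyte-frozen libraries and 5.88 and 6.12 in DMSO-frozen ones. Tested by limma camera, the list had an adjusted p of 2.47e-05, and adjusted p = 0.744 with an estimated correlation. Of 44 nuclear genes of the respiratory chain, 8 rose and 3 fell, against 4 and 3 adjusted over the list alone, with limma camera giving adjusted p = 0.0250, and adjusted p = 0.841 with an estimated correlation. Markers of mesenchymal stromal cells went both ways, with 6 of 24 rising and 11 falling, and 6 rising and 12 falling adjusted over the list alone. ANPEP fell 1.98-fold, CD44, the hyaluronan receptor, 1.79-fold, ALCAM 1.72-fold and PDGFRA, a receptor for platelet-derived growth factor, 1.80-fold. Extracellular matrix genes also went both ways, with 7 of 37 rising and 9 falling, and 7 rising and 10 falling adjusted over the list alone, as with COL6A3, which fell 1.98-fold, and FBN1, a microfibril protein, which fell 1.61-fold. The last 2 lists did not pass limma camera, with adjusted p = 0.156 for the markers and 0.639 for the matrix.

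Measures of RNA composition moved with the same libraries. The nuclear RNAs MALAT1 and NEAT1 took 0.895% ± 0.0509 (SD, n = 3) of counts in osmolyte-frozen and 0.422% ± 0.0414 (SD, n = 2) in DMSO-frozen libraries, where MALAT1 was 2.05-fold higher in the former and NEAT1 1.92-fold. Of 9 nuclear-retained and RNA-quality transcripts, 3 rose, also adjusted over the list alone, with limma camera giving adjusted p = 0.0245, and adjusted p = 0.305 with an estimated correlation. Of 12 pluripotent stem cell markers measured, 3 rose, also adjusted over the list alone: POU5F1 2.07-fold, DPPA4 1.498-fold and ESRG 1.41-fold. POU5F1, whose reads may be shared with processed copies, stood at 4.81 ± 0.627 CPM (SD, n = 3) against 2.33 ± 0.287 CPM (SD, n = 2). Limma camera gave the marker list an adjusted p of 0.0250, and adjusted p = 0.305 with an estimated correlation. The sum of counts was 65.3% ± 1.51 (SD, n = 3) of the total behind the authors' RPKM values in osmolyte-frozen libraries and 72.7% ± 0.636 (SD, n = 2) in DMSO-frozen ones.

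In all, edgeR quasi-likelihood found 2121 genes higher and 2563 lower in osmolyte-frozen cells among 15564 tested, of which 370 and 132 changed at least 2-fold. Of the 35 lists, limma camera called 9 higher and 4 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.139, while fry, which does not compare a list with other genes, called 12. The direction of small changes rested on the scaling: with library totals alone 2571 genes were higher and 1985 lower, or 56.4% higher against 45.3%. Without the library frozen in DMSO at 0 h, 2136 genes passed in place of 4684, with the lone DMSO-frozen library assumed to vary like the other groups.

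**Figure D3:**
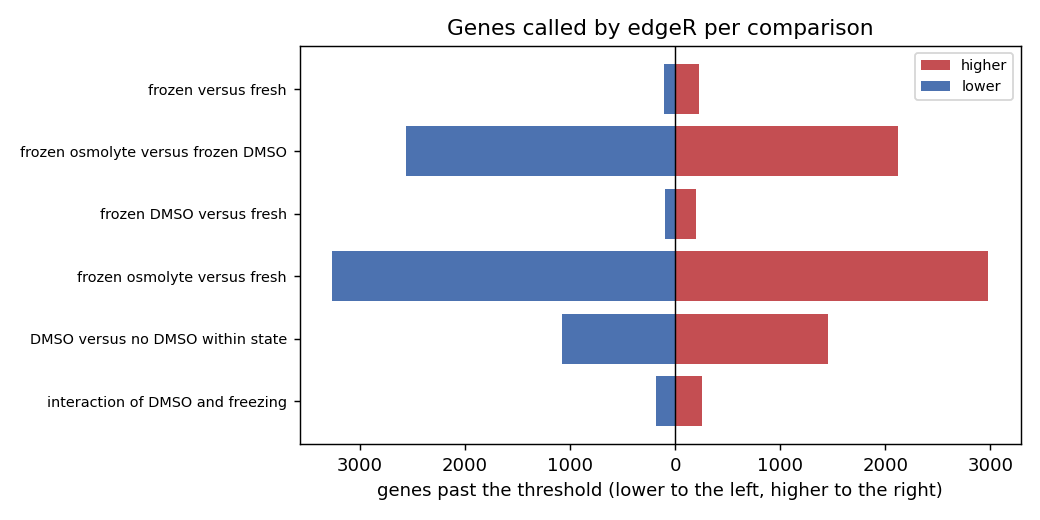
Numbers of genes past the Benjamini-Hochberg threshold of 0.05 by edgeR quasi-likelihood (horizontal axis) in each of the 6 tested comparisons (vertical axis). Bars for genes higher run to the right and bars for genes lower to the left. The bars for osmolyte-frozen against DMSO-frozen libraries stand at 2121 and 2563 genes and those for DMSO-frozen against fresh libraries at 195 and 96.

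Cells frozen in DMSO were compared with fresh cells to see what differed after freezing in the conventional solution. Only 1 of the 3 fresh libraries had DMSO, so freezing was not fully separated from exposure to DMSO. NTN1, the guidance protein netrin 1, was 4.60-fold higher after freezing, at 5.75 ± 1.27 CPM (SD, n = 2) against 1.24 ± 0.542 CPM (SD, n = 3). DKK2, a secreted regulator of WNT signalling, was 4.12-fold higher, at 18.3 ± 2.62 CPM (SD, n = 2) against 4.42 ± 1.29 CPM (SD, n = 3). CADM1, a cell adhesion molecule, was 2.69-fold higher, at 87.6 ± 4.93 CPM (SD, n = 2) against 32.5 ± 2.86 CPM (SD, n = 3). TNFRSF11B, which encodes osteoprotegerin, a decoy receptor that limits bone resorption, was 2.12-fold lower, at 14.8 ± 0.636 CPM (SD, n = 2) against 31.4 ± 5.17 CPM (SD, n = 3). By edgeR quasi-likelihood the adjusted p was 0.00458 for NTN1, 0.00106 for DKK2 and 6.25e-08 for CADM1. CLSTN2 rose 3.45-fold, B3GALT2, a galactosyltransferase, 3.00-fold, LRRN1 2.73-fold, NTRK3, a neurotrophin receptor, 2.58-fold and APLN, the peptide apelin, 2.39-fold. GAS1 rose 2.28-fold, COL14A1, a collagen, 2.24-fold, CELF2, a splicing regulator, 2.18-fold and FAT3, a protocadherin, 2.17-fold. SAMD11 fell 2.23-fold, ANXA10, an annexin, 2.19-fold, MALL 2.07-fold, LY6K 1.99-fold, PLEKHA6 1.97-fold, KRT19, a keratin, 1.94-fold and CRIP1 1.904-fold. NMNAT2 fell 1.89-fold, CRYAB, a small heat shock protein, 1.84-fold, ACE, the angiotensin-converting enzyme, 1.82-fold and RNF112 1.82-fold.

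Of 37 extracellular matrix genes 4 were higher in DMSO-frozen than in fresh cells, with 14 rising and 1 falling adjusted over the list alone. MMP2, a matrix protease, rose 1.44-fold, THBS2, a thrombospondin, 1.41-fold, TIMP2, an inhibitor of matrix proteases, 1.31-fold and TNC, tenascin C, 1.26-fold. The adjusted p by limma camera was 2.13e-05, and adjusted p = 0.600 with an estimated correlation. Relative to each gene's mean over all libraries, the list's mean log2 level at 0 h was 0.0178 in DMSO-frozen and -0.000756 in fresh cells. At 1 h it was 0.147 in DMSO-frozen cells, against -0.108 with DMSO and -0.186 in medium in fresh cells, so the difference lay mostly between the 1 h libraries. Of 14 muscle and contractile genes 3 rose, also adjusted over the list alone, namely ACTG2 1.60-fold, ACTA2 1.38-fold and CNN1 1.35-fold, with limma camera giving adjusted p = 0.0100, and adjusted p = 0.558 with an estimated correlation. Of 25 NRF2 and oxidant response genes 1 fell, and 3 fell adjusted over the list alone. Limma camera placed that list lower (adjusted p = 3.55e-06, and adjusted p = 0.217 with an estimated correlation). The member that fell over all genes was NQO1, 1.34-fold. Immediate early genes were lower than in the 2 fresh libraries without DMSO, but not than in the one with it. Their mean log2 level, relative to each gene's mean over all libraries, was -0.650 and -0.617 in the DMSO-frozen libraries, against 0.339 in fresh 0 h, 1.13 in fresh 1 h medium and -0.669 in fresh 1 h DMSO. Among the 42 genes the median log2 change was -0.88, with 0 past the threshold by edgeR over all genes or adjusted over the list alone, 7 lower at an unadjusted p under 0.05 and 4 lower by DESeq2. Limma camera gave that list an adjusted p of 6.58e-13, and adjusted p = 0.600 with an estimated correlation. In all, 195 genes were higher and 96 lower by edgeR quasi-likelihood, 30 and 12 of them at least 2-fold. The total of 291 came to 91 without the library frozen in DMSO at 1 h and to 99 without the one at 0 h, each time with the lone DMSO-frozen library assumed to vary like the other groups.

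Osmolyte-frozen cells were compared with the same 3 fresh libraries. The series has no library of unfrozen cells in SMC, SGC or SGI, so freezing and exposure to these solutions cannot be told apart. ELN was 36.2-fold higher than in fresh cells, at 38.6 ± 6.53 CPM (SD, n = 3) against 1.07 ± 0.179 CPM (SD, n = 3), with an adjusted p of 2.15e-12 by edgeR quasi-likelihood. NTN1 rose 16.6-fold, DKK2 11.4-fold, INHBB 9.82-fold, ASPN, the small matrix proteoglycan asporin, 9.54-fold, and NUPR1 7.76-fold. BMP4, a bone morphogenetic protein, rose 7.42-fold and NOG, noggin, which binds such proteins, 6.30-fold. ITIH3 rose 6.95-fold, CHAC1 6.55-fold, FAM84B 6.40-fold and B3GALT2 6.36-fold. PLEKHA6 was 7.80-fold lower, at 6.27 ± 0.591 CPM (SD, n = 3) against 48.9 ± 1.38 CPM (SD, n = 3), with an adjusted p of 1.53e-13 by edgeR quasi-likelihood. ANXA10 fell 8.02-fold, NMNAT2 6.47-fold, EREG, a ligand of the EGF receptor family, 6.36-fold, and CHI3L1 5.86-fold. ENPP2 fell 5.57-fold, HAS2 5.48-fold, MYPN 5.40-fold, SCN3A 4.55-fold, BEX1 4.39-fold and LOC152742 4.39-fold. EGR3, an immediate early factor, fell 7.37-fold, but its fresh libraries ran from 5.87 CPM with DMSO through 24.0 CPM at 0 h to 49.1 CPM in medium, against 3.22 to 3.82 CPM in the osmolyte-frozen ones. Its log2 change of -2.88 (adjusted p = 0.0413 by edgeR) came to -2.07 without fresh 1 h medium (adjusted p = 0.0781 by edgeR). It did not pass without fresh 0 h either, nor without any 1 of the 5 frozen libraries, with adjusted p by edgeR from 0.0712 to 0.125.

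Cell cycle genes were lower in osmolyte-frozen than in fresh cells, with 25 of 40 falling and 28 adjusted over the list alone, and limma camera gave adjusted p = 7.73e-08, and adjusted p = 0.650 with an estimated correlation. Of 28 hypoxia and glycolysis genes, 18 fell and 5 rose, or 19 and 5 adjusted over the list alone, with limma camera giving adjusted p = 0.000322, and adjusted p = 0.153 with an estimated correlation. Of 25 NRF2 and oxidant response genes, 15 fell and 1 rose, or 16 and 2 adjusted over the list alone, with limma camera giving adjusted p = 5.65e-06, and adjusted p = 0.117 with an estimated correlation. Muscle and contractile genes rose in 10 of 14 cases, also adjusted over the list alone, and limma camera gave adjusted p = 9.22e-07, and adjusted p = 0.117 with an estimated correlation. Of 24 amino acid response genes, 14 rose, while 15 rose and 1 fell adjusted over the list alone, with limma camera giving adjusted p = 9.11e-07, and adjusted p = 0.530 with an estimated correlation. Markers of mesenchymal stromal cells fell in 13 of 24 cases and rose in 5, or 14 and 5 adjusted over the list alone, and limma camera gave adjusted p = 0.0410, and adjusted p = 0.650 with an estimated correlation. Pluripotent markers and nuclear RNAs moved in the same libraries. Of 12 pluripotent markers 7 were higher, also adjusted over the list alone, with a median log2 change of 0.51 and limma camera giving adjusted p = 0.0678, and adjusted p = 0.474 with an estimated correlation. Of 9 nuclear-retained and RNA-quality transcripts 4 were higher, also adjusted over the list alone, with a median log2 change of 0.46 and limma camera giving adjusted p = 0.125, and adjusted p = 0.530 with an estimated correlation. MALAT1 and NEAT1 took 0.895% ± 0.0509 (SD, n = 3) of counts in osmolyte-frozen and 0.509% ± 0.0513 (SD, n = 3) in fresh libraries. By edgeR quasi-likelihood 2974 genes were higher and 3262 lower, 661 and 268 of them at least 2-fold.

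Both frozen groups were set against the same fresh libraries, so their changes share the chance values of those libraries. Of 195 genes higher in DMSO-frozen cells, 178 were also higher in osmolyte-frozen cells, where independent lists would share 37.3. Of 96 lower genes, 91 were also lower, where independent lists would share 20.1. Over both directions together, 6 genes passed in both comparisons with opposite signs. The log2 fold changes of the 2 comparisons had a correlation across genes, which are not independent replicates, of 0.503, against a median of 0.453 and a highest value of 0.479 in 100 simulations of unchanged groups. Their covariance was 0.101, against a median of 0.0224 and a highest value of 0.0247 in the simulations. The observed changes came from the edgeR fit, but the simulated ones from log2 CPM with a prior count of 2, which shrinks weakly expressed genes. The correlations and covariances are thus not on the same scale, and their gap cannot be read as an excess. The same sign was seen in 62.2% of genes, against 64.9% in the simulations. With 3 fresh libraries the controls could not be split, and the overlaps were not simulated with shared controls. How much of the overlap and of the correlation comes from the shared controls, up to all of it, is thus not known.

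All 5 frozen libraries were also compared with the 3 fresh ones, whatever the solution. NTN1 was 11.8-fold higher in frozen cells, at 14.7 ± 8.62 CPM (SD, n = 5) against 1.24 ± 0.542 CPM (SD, n = 3). DKK2 rose 8.49-fold, ASPN 7.39-fold, B3GALT2 5.01-fold, CLSTN2 4.92-fold, NOG 4.83-fold and LRRN1 4.802-fold. CELF2 rose 4.17-fold, GAS1 3.95-fold, CLDN1, a tight junction protein, 3.63-fold and the long noncoding RNA MIAT 3.58-fold. EGR3 was 7.84-fold lower, at 3.35 ± 0.576 CPM (SD, n = 5) against 26.3 ± 21.7 CPM (SD, n = 3), where the fresh libraries spread widely. MALL was 2.33-fold lower, at 8.39 ± 1.20 CPM (SD, n = 5) against 19.6 ± 1.22 CPM (SD, n = 3). LY6K fell 2.74-fold, ACE 2.73-fold, SAMD11 2.72-fold, LAMB3, a laminin chain, 2.47-fold, ALDH1A3, an enzyme of retinoic acid synthesis, 2.41-fold and ID1, an inhibitor of helix-loop-helix factors, 2.35-fold. CHST1 fell 2.32-fold, EFCAB4A 2.15-fold, CAMK2N1 2.14-fold and SLC6A6 2.12-fold. By edgeR quasi-likelihood the adjusted p was 0.0426 for NTN1, 0.00925 for ASPN, 0.0404 for EGR3 and 0.00362 for MALL. These calls depended on single libraries. With each library left out in turn, 111 of 192 values of the 24 genes named for this comparison no longer passed by edgeR. Without fresh 1 h medium 0 genes passed by edgeR, with 2234 at an unadjusted p under 0.05 and 452 by DESeq2.

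Among 40 cell cycle genes, 0 passed over all genes by edgeR in frozen against fresh cells, 15 fell at an unadjusted p under 0.05, 6 by DESeq2 and 8 adjusted over the list alone. By limma camera the list was lower (adjusted p = 1.27e-07, and adjusted p = 0.800 with an estimated correlation). The fall lay mostly in the osmolyte-frozen libraries. Relative to each gene's mean over all libraries, the mean log2 level was -0.254 to -0.0868 in these. It was 0.00361 and 0.123 in cells frozen in DMSO at 1 h and 0 h, and 0.0577 to 0.209 in fresh cells. Among 25 NRF2 and oxidant response genes, edgeR likewise called 0 over all genes, with 15 lower at an unadjusted p under 0.05, 7 lower by DESeq2 and 13 lower adjusted over the list alone, and limma camera gave adjusted p = 1.55e-05, and adjusted p = 0.800 with an estimated correlation. Their mean log2 level, taken in the same way, was -0.325 to -0.219 in osmolyte-frozen libraries. It was 0.0621 and 0.0484 in cells frozen in DMSO at 1 h and 0 h, and 0.211 to 0.256 in fresh cells, so the fall was larger with the osmolyte solutions. Of 42 immediate early genes 2 fell, and 3 fell adjusted over the list alone. The 2 that fell over all genes were EGR3 and DUSP2, a phosphatase of MAP kinases, at 3.86-fold. The adjusted p of that list by limma camera was 0.0296, and adjusted p = 0.844 with an estimated correlation. The fresh libraries stood apart in this list, with mean log2 levels relative to each gene's mean of 1.13 in 1 h medium, 0.339 at 0 h and -0.669 in 1 h DMSO, the last near the DMSO-frozen libraries and below the osmolyte-frozen ones. In all, edgeR quasi-likelihood called 231 genes higher and 104 lower, 87 and 29 of them at least 2-fold. The total of 335 came to 24 without fresh 0 h, 22 without fresh 1 h DMSO, 0 without fresh 1 h medium (edgeR; 2234 at an unadjusted p under 0.05 and 452 by DESeq2), 93 without SMC, 106 without SGC and 60 without SGI, while it was 1154 without frozen 1 h DMSO and 1758 without frozen 0 h DMSO. With the frozen groups fitted apart and their mean set against fresh cells, 3151 genes passed.

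Of 5 measures of library composition, 0 passed the two-sided exact permutation test of frozen against fresh libraries over 56 splits, before or after Benjamini-Hochberg adjustment over the 5. The smallest p that 56 splits allow is too large for 1 measure alone to pass after that adjustment. Ribosomal protein genes took 3.81% ± 0.445 (SD, n = 5) of counts in frozen and 3.66% ± 0.257 (SD, n = 3) in fresh libraries (exact permutation p = 0.607, adjusted p = 0.759). MALAT1 and NEAT1 took 0.706% ± 0.262 (SD, n = 5) and 0.509% ± 0.0513 (SD, n = 3) (exact permutation p = 0.321, adjusted p = 0.536). The 10 most abundant genes took 16.9% ± 1.10 (SD, n = 5) and 15.3% ± 1.05 (SD, n = 3) (exact permutation p = 0.107, adjusted p = 0.268). Genes with a count above 0 numbered 17877 ± 141 (SD, n = 5) and 17613 ± 110.3 (SD, n = 3) (exact permutation p = 0.0714, adjusted p = 0.268). Without frozen 0 h DMSO the exact permutation p was 0.0286, the smallest that the fewer splits then possible allow. Counts were 68.2% ± 4.18 (SD, n = 5) and 68.6% ± 2.16 (SD, n = 3) of the total behind the authors' RPKM values (exact permutation p = 0.946, adjusted p = 0.946). In this share the frozen groups lay on opposite sides of the fresh libraries, at 65.3% with osmolyte solutions and 72.7% with DMSO. The same held for MALAT1 and NEAT1, at 0.895% and 0.422%, so pooling the frozen groups can hide such differences.

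Libraries with DMSO, 1 fresh and 2 frozen, were compared with the 5 without, allowing for the state of the cells. Those without DMSO were 2 fresh libraries and the 3 osmolyte-frozen ones, so among frozen cells the difference is that between DMSO and the osmolyte solutions. Immediate early genes were lower with DMSO: 19 of 42 fell, and 25 adjusted over the list alone, with a median log2 change of -1.04. DUSP1, a phosphatase that ends MAP kinase signals, was 4.49-fold lower, at 61.8 ± 6.54 CPM (SD, n = 3) against 278 ± 110.2 CPM (SD, n = 5), and NR4A1, a nuclear receptor, 5.31-fold lower, at 5.999 ± 1.55 CPM (SD, n = 3) against 45.2 ± 39.97 CPM (SD, n = 5). JUNB, a subunit of the AP-1 factor, fell 2.64-fold, IER2 2.56-fold and CYR61, a secreted matricellular protein, 1.93-fold. SGK1, a kinase regulated by glucocorticoids, was 2.08-fold lower, at 62.0 ± 5.79 CPM (SD, n = 3) against 127 ± 21.4 CPM (SD, n = 5), CTGF, connective tissue growth factor, fell 2.29-fold, and EDN1, endothelin 1, 2.34-fold. By edgeR quasi-likelihood the adjusted p was 0.0315 for DUSP1, 0.0490 for NR4A1, 4.52e-05 for SGK1 and 0.00233 for CTGF. The list was lower by limma camera (adjusted p = 3.60e-21, and adjusted p = 0.652 with an estimated correlation). In the same fit ELN was 7.84-fold lower, NUPR1 3.96-fold, INHBB 3.90-fold, KRT17 3.26-fold, NTN1 3.22-fold and FAM84B 2.26-fold, and for ELN, NUPR1, INHBB, KRT17 and FAM84B this came mostly from high levels in the osmolyte-frozen libraries. There ELN lay at 31.1 to 43.0 CPM, NUPR1 at 8.22 to 9.60 CPM, INHBB at 10.27 to 10.67 CPM and KRT17 at 7.98 to 8.66 CPM. In fresh cells ELN lay at 0.910 CPM with DMSO against 1.03 and 1.26 CPM without, NUPR1 at 0.955 against 1.16 and 1.31 CPM, INHBB at 0.819 against 1.39 and 0.970 CPM, KRT17 at 1.91 against 2.10 and 2.52 CPM, and FAM84B at 2.68 against 2.68 and 2.76 CPM. In fresh cells NTN1 lay at 0.773 CPM (95% interval 0.450 to 1.24) with DMSO. It lay at 1.83 CPM (95% interval 1.32 to 2.49) at 0 h and 1.12 CPM (95% interval 0.707 to 1.67) in medium. The intervals with DMSO and in medium overlap, so that difference may be counting error. SCN3A rose 2.70-fold, ANGPT1 2.45-fold, NMNAT2 2.38-fold, MYPN 2.28-fold, AOX1, aldehyde oxidase, 2.27-fold and THSD7A 2.21-fold. SLC16A14 rose 1.94-fold, CLCN4 1.93-fold, KITLG, the ligand of the KIT receptor, 1.89-fold, TRHDE 1.88-fold, LNPEP 1.86-fold and EBF2 1.84-fold.

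Of 74 ribosomal protein genes 26 fell with DMSO, and 41 adjusted over the list alone, with limma camera giving adjusted p = 6.64e-13, and adjusted p = 0.652 with an estimated correlation. Of 24 amino acid response genes 11 fell, and 12 adjusted over the list alone, with limma camera giving adjusted p = 1.29e-06, and adjusted p = 0.652 with an estimated correlation. Of 40 cell cycle genes 12 rose, and 14 adjusted over the list alone, with limma camera giving adjusted p = 2.72e-07, and adjusted p = 0.652 with an estimated correlation. TGF-beta targets fell in 5 of 19 cases, against 7 falling and 1 rising adjusted over the list alone, and muscle genes fell in 5 of 14, also adjusted over the list alone. The adjusted p by limma camera was 0.000132 for the former and 0.000452 for the latter, and both had adjusted p = 0.652 with an estimated correlation. For muscle, amino acid response and cell cycle genes the difference lay mostly in the osmolyte-frozen libraries. Relative to each gene's mean over all libraries, the mean log2 level of the muscle genes was -0.368 in fresh cells with DMSO against -0.289 and -0.362 without, and 0.421 to 0.543 in osmolyte-frozen libraries. That of the amino acid response genes was -0.336 against -0.298 and -0.287, and 0.587 in SGC and 0.463 in SGI, with SMC lower than these but above the fresh and DMSO-frozen libraries. That of the cell cycle genes was 0.209 in fresh cells with DMSO against 0.0577 and 0.187 without, and -0.254 to -0.0868 in osmolyte-frozen libraries. Pluripotent markers moved with these lists, with 2 of 12 lower with DMSO, also adjusted over the list alone, a median log2 change of -0.45 and limma camera giving adjusted p = 0.0362, and adjusted p = 0.652 with an estimated correlation. So did nuclear-retained and RNA-quality transcripts, with 4 of 9 lower, also adjusted over the list alone, and limma camera giving adjusted p = 0.0320, and adjusted p = 0.652 with an estimated correlation. By edgeR quasi-likelihood 1452 genes were higher and 1075 lower with DMSO, 22 and 128 of them at least 2-fold. The total of 2527 came to 17 without frozen 0 h DMSO, 25 without frozen 1 h DMSO, 691 without SGI and 875 without SGC, and to 4648 without fresh 1 h DMSO, while hold time as a covariate gave 1332.

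**Figure D4:**
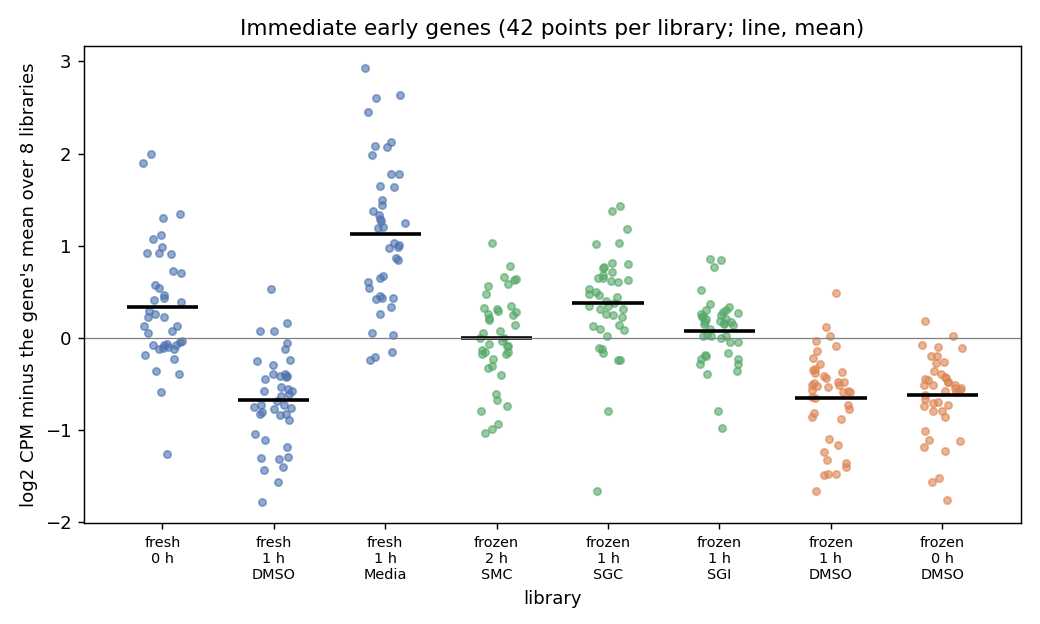
Log2 CPM of 42 immediate early genes in each of the 8 libraries (horizontal axis), each minus its gene's mean over all libraries (vertical axis), with 1 point per gene and a line at the library's mean. The line stands at 1.13 for fresh 1 h medium and at -0.669, -0.650 and -0.617 for the 3 libraries with DMSO.

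The interaction term set the difference between DMSO and osmolyte solutions in frozen cells against that between DMSO and no DMSO in fresh cells, so it is not 1 DMSO difference in 2 states. The median log2 term was -0.592 for muscle and contractile genes and -0.466 for amino acid response genes. Nuclear-retained and RNA-quality transcripts moved the same way, with a median of -0.352. Fresh cells with DMSO were 1 library, assumed to vary like the libraries of the other conditions. With that assumption the term passed for 437 genes by edgeR quasi-likelihood, 258 with a positive and 179 with a negative term. With library totals alone the numbers were 164 and 242, or 40.4% positive in place of 59%. For ELN the term was -3.13 (adjusted p = 0.00032 by edgeR), and for PLEKHA6 it was 1.99 (adjusted p = 2.69e-06 by edgeR). Muscle and contractile genes had negative terms in 6 of 14 cases, and 9 adjusted over the list alone, with limma camera giving adjusted p = 2.75e-09, and adjusted p = 0.180 with an estimated correlation. Amino acid response genes had negative terms in 2 of 24 cases, and 12 adjusted over the list alone, with limma camera giving adjusted p = 6.25e-09, and adjusted p = 0.448 with an estimated correlation.

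Conditions with 1 library each were also set side by side, with no replicate check and no test. Folds here include the prior count of 2, while the printed CPM levels do not. In fresh cells after 1 h, 60 genes were at least 2-fold higher and 99 at least 2-fold lower with DMSO than in medium. HES1, a target of Notch signalling, was 20.4-fold lower, at 3.87 CPM (95% interval 3.09 to 4.78) against 79.7 CPM (95% interval 75.9 to 83.7), CXCL2, a chemokine, 15.1-fold, ATF3, a stress-induced factor, 14.99-fold, FOSB 14.7-fold and NR4A1 13.4-fold lower. Of 42 immediate early genes 40 were lower, 35 of them at least 2-fold, and the median log2 ratio of -1.70 lay at percentile 0 of random lists matched on expression. SGCA, sarcoglycan alpha, was 8.20-fold higher with DMSO, SLC16A7, a monocarboxylate transporter, 2.57-fold, TXNIP, a regulator of glucose uptake, 2.43-fold and ZBED6 2.38-fold. Fresh cells after 1 h in medium differed from those at 0 h by 54 genes higher and 54 lower, with HES1 7.78-fold, BHLHE40 3.75-fold, IL8, a chemokine, 3.74-fold and ATF3 3.68-fold higher. SLC16A7 was 2.64-fold, ZSCAN23 2.50-fold and TXNIP 2.34-fold lower. Immediate early genes had a median log2 ratio of 0.80, at percentile 100, with 16 of 42 at least 2-fold higher. Cells frozen in DMSO and held for 1 h differed from those at 0 h by 31 genes higher and 20 lower. SGCA was 3.09-fold and PCSK1N 2.31-fold higher, while EGR1 was 2.10-fold and FOS 1.998-fold lower. The median log2 ratio of the immediate early genes was 0.02.

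After 1 h with DMSO, frozen cells had 81 genes at least 2-fold higher and 49 lower than fresh cells, with NTN1 8.18-fold, DKK2 5.23-fold, ASPN 3.99-fold and GAS1 3.61-fold higher. NMNAT2 was 2.48-fold, EGR3 2.41-fold, MYPN 2.23-fold and TNFRSF11B 2.14-fold lower. Among frozen cells held for 1 h, those in SGC had 389 genes higher and 165 lower than those in DMSO, and those in SGI 506 and 139. ELN was 10.5-fold higher in SGC and 7.82-fold in SGI, TNNT2, cardiac troponin T, 9.52-fold and 8.53-fold, and CHAC1 6.74-fold and 5.85-fold. HES1 was 7.39-fold and DUSP1 6.69-fold higher in SGC, and LINC00312 5.21-fold higher in SGI. SGCA was 7.08-fold lower in SGC and 6.38-fold in SGI, COL2A1, a cartilage collagen, 5.59-fold lower in SGC and ENPP2 5.10-fold lower in SGI. SGC and SGI differed directly by 16 genes higher and 52 lower in SGC, with NR4A1 2.04-fold, ATF3 1.97-fold and ZFP36 1.82-fold higher and MUC6 2.30-fold, IFNE 1.81-fold and HAS2 1.75-fold lower. Extracellular matrix genes were higher in SGC than in SGI for 35 of 37, with a median log2 ratio of 0.16 at percentile 100. Cell cycle genes were lower for 36 of 40, with a median of -0.18 at percentile 0. In this pair 10 of 35 lists lay near the top of the random lists and 2 near the bottom. An extreme percentile thus does not mark these lists as differing between the solutions. Cells in SMC were held for 2 h, so the time differs from that of the DMSO library at 1 h, against which 305 genes were higher and 119 lower, with ELN 10.8-fold, LINC00312 6.58-fold and KRT17 5.73-fold higher and CHI3L1 4.25-fold and HAS2 4.09-fold lower.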

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

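Among the tests given here, those of a separate culture, of dilution by other cells and of splits that kept the osmolyte-frozen libraries together were chosen only after the result was seen. A difference between groups drew attention to 437 genes, for which the interaction of DMSO and freezing passed by edgeR quasi-likelihood. The term is the log2 difference of DMSO-frozen from osmolyte-frozen cells minus that of fresh cells with DMSO from fresh cells without, so its sides do not compare the same thing. The fresh side with DMSO is 1 library, whose spread was assumed to be that of the other conditions, so the term does not show that the effect of DMSO depends on freezing. It was -3.13 for ELN (adjusted p = 0.00032), -2.73 for CHAC1 (adjusted p = 0.0161 by edgeR) and -2.32 for ADM2 (adjusted p = 3.89e-05 by edgeR). It was 1.99 for PLEKHA6 (adjusted p = 2.69e-06 by edgeR), 2.09 for CHI3L1 (adjusted p = 0.00032 by edgeR) and 2.06 for ENPP2 (adjusted p = 0.000464 by edgeR). For TRH the term was 1.82 (adjusted p = 3.62e-05 by edgeR), for EREG 2.15 (adjusted p = 0.0475 by edgeR), for DUSP6 1.71 (adjusted p = 0.0489 by edgeR) and for IL1R1 1.65 (adjusted p = 0.000352 by edgeR).

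Of 56 splits of the libraries into 5 and 3, 2 gave at least the 335 genes of frozen against fresh cells, the real one included. The other such split, with 6244 genes, set the 3 osmolyte-frozen libraries against the remaining 5, which points to a structure of the samples. A split that divides those 3 libraries counts that structure as spread, so it says little about chance. Of the 56 splits 11 kept them on one side, too few for a share under 0.05, and 2 of the 11 gave as many genes. Of 30 splits that kept the state of the cells, 1, the real one, gave the 2527 genes of DMSO against no DMSO, and the highest of the others gave 16. Of these, 3 splits kept the osmolyte-frozen libraries together, again too few for a share under 0.05. For osmolyte-frozen against fresh cells the 10 splits are too few for a share under 0.05: 1 of them, the real one, gave 6236 genes, and the highest other gave 0 by edgeR, where the most at an unadjusted p under 0.05 was 1107 and the most by DESeq2 was 37.

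Osmolyte-frozen and DMSO-frozen libraries differed by 4684 genes. After a correction for GC content 82% of the called genes with a GC value kept their call and direction, after one for coding length 84% of the called genes did, and without the 10 most abundant genes 99.6% did, so none of these accounts for most of the difference, though 1361 genes were then higher and 3012 lower under the first correction, and 1646 and 3558 under the second. For the 132 genes at least 2-fold lower, dilution by other cells would lower abundant genes alike, apart from genes those cells share. Of the 100 most abundant genes of DMSO-frozen cells, 0 lay at or below a log2 change of -1. How many of the 100 such cells would share is not known, so this speaks only against dilution by cells that share few of them. A milder dilution, for genes that fell less, was not tested. Cells of another type, with a largest marker median of 0.56 for pluripotent markers, and loss of cytoplasmic RNA, with a median of 0.40 for nuclear-retained RNAs, cannot be told apart from an effect of the solutions, since both medians lie between the values that would decide. A separate culture or preparation stays open as well, since the lowest correlation between osmolyte-frozen libraries was 0.99 and the highest with a DMSO-frozen library 0.985, and cooling rate and solution went together, so an effect of either on the cells was not tested.

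Immediate early genes were lower in the 3 libraries with DMSO. The tables argue against hold time alone, since with hold time as a covariate the median log2 change was -0.97, with 12 of 42 genes falling by edgeR and limma camera giving adjusted p = 4.24e-24, and adjusted p = 0.673 with an estimated correlation. The fresh library with DMSO alone does not carry it either, since without that library the median was -0.83, with 13 genes falling by edgeR and limma camera giving adjusted p = 1.09e-10, and adjusted p = 0.715 with an estimated correlation. Without that library the DMSO term rests only on DMSO-frozen against osmolyte-frozen cells. It is thus the contrast given earlier with a median of 0.83 for osmolyte over DMSO, with the sign turned, and no separate evidence. A hypothesis left open is that DMSO may dampen the induction of these genes during handling. In frozen cells DMSO goes with cooling rate, and in fresh cells 1 library with DMSO, at a mean log2 level of -0.669 relative to each gene's mean, stands against 2 without, at 0.339 and 1.13, so that hypothesis was not separated from handling that differed between vials.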

How the results depend on the processing

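Among the alternatives given here, halved counts and leaving out each library for the gene lists were chosen after seeing the data. No paired analysis was possible because each condition had 1 library and the labels give no replicate numbers. Leaving out mitochondrially encoded genes was not run, since the table lists none. Over 3220 values of named genes under these alternatives 2905 kept their direction and their side of the threshold, 315 kept their direction but no longer passed and 0 reversed. These genes were picked from the same data, largely as big changes past the threshold, so reversals were unlikely from the start. Of the 315, 111 came from leaving out a library in frozen against fresh, 87 in DMSO against no DMSO, 37 in DMSO-frozen against fresh, 20 in osmolyte-frozen against DMSO-frozen and 7 in osmolyte-frozen against fresh cells. For frozen against fresh cells the 335 genes became 1451 by DESeq2, 154 with hold time as a covariate, 3151 with the mean of the frozen groups and 3217 in the additive fit with DMSO, and from 0 without fresh 1 h medium (edgeR; 2234 at an unadjusted p under 0.05 and 452 by DESeq2) to 1758 without frozen 0 h DMSO. The others were 24 without fresh 0 h, 22 without fresh 1 h DMSO, 93 without SMC, 106 without SGC, 60 without SGI and 1154 without frozen 1 h DMSO. For osmolyte-frozen against DMSO-frozen cells leaving out a library gave 2136, without frozen 0 h DMSO, to 5254 genes, and leaving out SMC for its hold time gave 1797 higher and 2913 lower. DMSO-frozen against fresh cells gave 496 genes by DESeq2 and from 91, without frozen 1 h DMSO, to 311 when a library was left out, with 99 without frozen 0 h DMSO. Osmolyte-frozen against fresh cells gave 5001 to 6080. DMSO against no DMSO gave 1332 genes with hold time as a covariate and from 17, without frozen 0 h DMSO, to 4648, without fresh 1 h DMSO, with 25 without frozen 1 h DMSO, 691 without SGI and 875 without SGC. The interaction gave 737 genes with no filter and 660 by DESeq2. Halved counts gave 306, 4791, 299, 6281, 2623 and 423 genes for frozen against fresh, osmolyte-frozen against DMSO-frozen, DMSO-frozen against fresh, osmolyte-frozen against fresh, DMSO and the interaction. For these changes the cause was not tested, apart from fewer libraries where 1 was left out.

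With an estimated correlation limma camera called 0 lists in place of 8 for frozen against fresh, 13 for osmolyte-frozen against DMSO-frozen and 14 for DMSO against no DMSO. Its lowest adjusted p was then 0.800, 0.139 and 0.652, and fry called 0, 12 and 0 lists. Leaving out a library gave 6 to 11, 9 to 14 and 10 to 15 lists. For the pairs a count of at least 20 or at least 200 in the higher library changes which genes are counted: 417 or 70 in place of 159 for fresh DMSO against medium, 330 or 41 in place of 108 for fresh medium against 0 h, 245 or 8 in place of 51 for frozen DMSO at 1 h against 0 h, and 353 or 40 in place of 130 for frozen against fresh cells with DMSO. Against DMSO it gave 955 or 264 in place of 554 for SGC, 1039 or 244 in place of 645 for SGI and 775 or 185 in place of 424 for SMC, and 265 or 3 in place of 68 for SGC against SGI. Leaving out a library moved the frozen minus fresh difference of the ribosomal share from 0.0383 to 0.306 percentage points, of MALAT1 and NEAT1 from 0.137 to 0.276, of the 10 most abundant genes from 1.08 to 2.12 and of genes detected from 216.6 to 324.1. Without frozen 0 h DMSO the difference in genes detected was 304.9, with a two-sided exact permutation p of 0.0286, the smallest that the fewer splits then possible allow. Depth limits the precision of weakly expressed genes. The 95% exact Poisson interval of ELN, for counting error only, ran from 0.652 to 1.54 CPM around 1.03 CPM in fresh 0 h and from 40.2 to 45.95 CPM around 43.0 CPM in SMC.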

Other observations

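Stress programmes beyond those of the report went both ways in osmolyte-frozen against DMSO-frozen cells. Of 23 genes of endoplasmic reticulum stress, 4 rose and 6 fell, or 5 and 8 adjusted over the list alone. DDIT3, a factor of prolonged stress, rose 1.94-fold, ATF4, the factor that drives the amino acid response, 1.52-fold and HERPUD1, which helps degrade misfolded proteins, 1.49-fold, while SEL1L, a part of the same degradation machinery, fell 1.70-fold. Of 24 targets of p53, 7 rose and 3 fell, also adjusted over the list alone. BBC3, which promotes apoptosis, rose 1.94-fold and GDF15, a secreted stress cytokine, 1.98-fold, while CCNG1, cyclin G1, fell 1.36-fold. Of 28 heat shock response genes, 2 rose and 8 fell, also adjusted over the list alone. The chaperones HSPA4, HSPD1 and HSPA8 fell 1.46-fold, 1.36-fold and 1.33-fold, and the small heat shock protein HSPB1 rose 1.58-fold. By limma camera none of these lists passed, with adjusted p = 0.383, 0.472 and 0.410 in that order.

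Adipogenic and chromatin genes were mostly lower among those that passed. Of 9 adipogenic markers 3 fell, also adjusted over the list alone: ZNF423, a factor of fat cell precursors, 1.91-fold, PPARG, the main factor of fat cell formation, 1.86-fold, and PLIN2, a coat protein of lipid droplets, 1.53-fold. Of 36 chromatin and DNA methylation enzymes, 8 fell and 2 rose, or 7 and 2 adjusted over the list alone, and DNMT1, the maintenance DNA methyltransferase, fell 1.57-fold. Limma camera gave adjusted p = 0.129 for the adipogenic list and 0.0978 for chromatin enzymes.

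SGCA, which encodes sarcoglycan alpha, lay at 5.09 CPM (95% interval 4.19 to 6.13) in fresh and 6.91 CPM (95% interval 5.87 to 8.07) in frozen cells held for 1 h with DMSO, and at 2.21 CPM (95% interval 1.67 to 2.87) in cells frozen in DMSO at 0 h. In the other libraries it lay between 0.582 CPM and 1.13 CPM. The gene sits on chromosome 17 from 48243366 to 48253293 in hg19, 8.16 kb from COL1A1, a strongly expressed collagen gene. A candidate explanation is that transcripts ran past the 3' end of strongly expressed neighbours. Weakly expressed genes downstream of a strong gene had a median log2 ratio, fresh DMSO over fresh medium at 1 h, 0.08 above that of genes near a strong gene's 5' end (95% bootstrap interval over genes 0.00699 to 0.153). The value itself lay below the bound set beforehand for excluding the explanation. The interval, which the rule set beforehand did not mention, reached above that bound. In that pair the downstream median of 0.0175 lay at percentile 79.3 of random genes matched on expression. For fresh DMSO at 1 h over fresh 0 h the downstream median was 0.0227, at percentile 99.98, against -0.0603 near a 5' end, and for cells frozen in DMSO at 1 h over 0 h it was 0.145, at percentile 100, against 0.0517. No bound was set beforehand for these pairs and no interval was computed for them, so read-through and a change of the gene itself cannot be told apart.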
